A study of Homo sapiens with 24 samples.

How the data were processed

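The samples were cultures of PC3 and LNCaP, established human prostate cancer lines, grown in 6-well plates and treated with Siomycin A or DMSO for 24 h or 48 h, with 3 arrays in each of the 8 groups. Total RNA was turned into biotin-labelled cRNA and hybridised to Illumina bead arrays, per the labels' protocols. Each sample was placed in its group by its labels, and each data column was matched to its sample by name. No value column was left without a sample (0 columns).

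Per the file headers, the deposited scanner values gave 1 intensity and 1 detection p-value for each of 47318 probes on each of the 24 arrays. The deposited intensities were on a linear scale, and their values showed neither background subtraction nor scaling between arrays. How the authors computed the detection p-value is not given in the sources used here. In the values it was small on both sides of the background, so that between 3215 and 4216 probes per array had a p under 0.01 while dimmer than background. The authors' processed table held log2 values, made with lumi per the submitters' processing notes, with the lumi version and settings not given in the sources used here. Set against the intensities of the same array, its log2 values had a rank correlation of 1 and columns with medians of 6.91. They differed by at most 0.00359 from intensities that were logged and quantile normalized without background correction. No genome build is named in the sources used here, so no coordinates are given.

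The background correction fixed before the data were examined was limma's neqc, which takes the background from detection p-values that fall with signal. Since the deposited p-values were two-sided, an adapted version was used. The background centre of an array was the median signal of probes with a detection p above 0.9, and its SD came from the probes dimmer than that centre. Centres lay between 97.7 and 116.4 and SDs between 8.49 and 11.61. The normexp model was then applied with an offset of 16, followed by log2 and quantile normalization between arrays. A probe counted as above background where its detection p was under 0.01 and its signal above the centre, and it was kept where this held on at least 3 arrays, which left 25215 probes. This departs from the fixed filter, which asked only for the p. Changes of low signals are understated by the offset. For arrays the number per group limits the precision.

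The probe list given for the platform names 30119 probes, of which 30111 had 1 gene symbol and 8 several, and the other 17199 probes were unnamed here. Of the probes with 1 gene, 30072 were found by gene number in a RefSeq table of the assembly GRCh38.p14, used for names and gene lengths only, 39 were not, and 0 symbols changed. The unit of the tests was the gene, represented by its kept probe with the highest mean over the 24 arrays. This gave 13344 genes from 17918 probes, and 3553 of these genes had more than 1 kept probe.

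Differences were tested with limma (lmFit and eBayes) on 8 group means over all 24 arrays, which left 16 residual degrees of freedom and 3.36 prior ones. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of a contrast, with calls at an adjusted p under 0.05. The contrasts were Siomycin against DMSO in each line at each time, the difference of these effects between times in each line, and their difference between lines at each time. Errors of log2 fold changes are limma's standard errors. Where a gene was not above background on any array of a group, its fold was given as a bound against the lowest signal above background on each array, or the gene's own signal there if higher. Smaller numbers of arrays above background are stated with the gene or at the end of its paragraph. For a difference of effects they were counted in all 4 groups, and a difference with a group below background is a fitted value, not a bound.

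For gene lists, 18 were fixed before the data were examined: mitosis and FOXM1 targets, proteasome subunits, DNA replication and G1/S, cytosolic heat shock, ATF4 integrated stress response, endoplasmic reticulum chaperones, NRF2 oxidative stress, p53 targets, apoptosis regulators, androgen receptor targets, cholesterol and fatty acid synthesis, metallothioneins and zinc, ubiquitin and autophagy, NF-kB and inflammatory, histones, immediate early, ribosome biogenesis, and glycolysis and hypoxia. The lists of line markers were fixed as well. Of 392 distinct genes in all lists, 346 were tested, 16 had no kept probe and 30 were not analysed here. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the 72 tests of 18 lists in 4 comparisons, and likewise over the 4 differences. With an estimated correlation all passing lists held in PC3 at 24 h and LNCaP at 24 h, and the losses elsewhere are stated beside each list. Where no count adjusted over the list alone stands beside a passing list in a comparison or difference, it equalled that over all genes. Median, mean and test differed in sign only in lists that did not pass: chaperones and histones in PC3 at 24 h, DNA replication, p53 and androgen receptor targets in PC3 at 48 h, and histones in LNCaP at 24 h. Among differences of effects this held for proteasome, apoptosis and androgen receptor lists between times in PC3, mitosis, apoptosis and NF-kB lists in LNCaP, and histones between lines at 24 h. Among passing lists, medians with genes below background in 1 group set to their bound moved most for immediate early genes in LNCaP at 48 h (0.19 as fitted, 0.36 with bounds), then for chaperones there (0.18 and 0.12).

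Genes to name were chosen by a rule fixed before the data were examined. It took MELK and FOXM1, and the 6 largest rises and falls per comparison among called genes whose 3 treated values all lay beyond the 3 control values. It also took up to 2 called members in each direction of both primary lists (mitosis and proteasome) and of each list that passed, the 4 largest differences in each direction per difference of effects, and the line markers. Placeholder names, XIST and Y-linked genes were left out. Genes named outside the rule are said to be so.

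The alternatives fixed before the data were examined were the authors' processed table, no background correction, an offset of 50, median centring, no filter on dim probes, only probes above background on all 24 arrays, and the mean of all probes of a gene. They also included limma's trend and robust options, array weights, the replicate number as a block, only the arrays of a comparison, line or time, leaving out each array in turn, an estimated correlation and the fry test for lists. Added after the data had been seen were normexp fitted to each array, a filter on either side of the background, the 24 h DMSO arrays as control of the 48 h arrays (for lists also in the difference between lines), and leaving out 2 arrays in doubt. These were PC3 Siomycin 48 h replicate 3, which had the lowest mean intensity (314.4), and LNCaP Siomycin 24 h replicate 1, from the group with the lowest correlation between replicates (0.981). No sample was left out of the tests as reported, and no pair of columns held identical values (0 pairs).

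The tests were run on simulated data with 200 of 13344 genes changed. At a 2-fold change 94.0% of the changed genes were called in the simulated PC3 24 h comparison, 89.6% in PC3 48 h, 88.1% in LNCaP 24 h and 94.0% in LNCaP 48 h. Among the calls 5.56%, 4.55%, 5.29% and 5.03% were false, in the same order. Of 200 random lists of 30 unchanged genes, 1.5%, 1%, 0.5% and 1.5% had a camera p under 0.05. The simulated genes varied independently of each other, and fewer were changed than were called in the data. The shares of lists thus do not show how camera behaves on lists of correlated genes. Computations used R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, and figures used Python 3.11.15 with matplotlib 3.10.9.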

Results

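Gene expression was measured in PC3 and LNCaP cells, 2 human prostate cancer cell lines, of which LNCaP carries an active androgen receptor and PC3 grows without androgen signalling. The cells had been exposed to Siomycin A, a thiopeptide antibiotic known to inhibit the proteasome and to lower expression of the transcription factor FOXM1 and the mitotic kinase MELK, or to its solvent DMSO, for 24 h or 48 h. The labels give the dose as 0.5 microM in the treatment protocol and as 5 microM in the sample titles. The sample descriptions and data column names write the protocol's digits without a decimal point. The dose is left open here. Each of the 8 groups (line, treatment and time) held 3 Illumina bead arrays, 24 in all, and nothing in the labels says whether the 3 replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical.

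The arrays had mean intensities from 314.4 to 498.8 over a background centred between 97.7 and 116.4, and between 17010 and 20101 of the 47318 probes lay above background. The mean number of probes above background ± SD was 19226 ± 345 in PC3 DMSO 24 h, 19939 ± 168 in PC3 Siomycin 24 h, 18975 ± 69.5 in PC3 DMSO 48 h and 17668 ± 578 in PC3 Siomycin 48 h. In LNCaP it was 17600 ± 112, 18174 ± 131, 17970 ± 12.5 and 18291 ± 164 in the same order (n = 3 arrays each). Every array correlated best with an array of its own group. Known genes of the lines separated them: TMPRSS2, an androgen-driven protease, had a log2 level of 11.30 ± 0.86 (SD, 12 arrays) in LNCaP and 5.47 ± 0.40 in PC3, while VIM, the filament protein vimentin, had 13.32 ± 0.11 in PC3 and 7.92 ± 0.10 in LNCaP. The arrays of the marker's own line lay above all arrays of the other line for 7 of 8 measured LNCaP markers (KLK3, KLK2, TMPRSS2, SLC45A3, STEAP2, ACP3 and FOLH1) and for 10 of 10 PC3 markers (VIM, CAV1, CAV2, CD44, ANXA1, AXL, MET, GSTP1, PLAU and CXCL8). The exception was HOXB13, at 9.09 ± 0.17 in LNCaP and 8.55 ± 0.91 in PC3.

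The treatment was aimed, as far as the compound is known, at FOXM1 and MELK, and both were therefore examined in every comparison of Siomycin with DMSO. MELK (probe ILMN_2212909) was lower in all 4 comparisons, with log2 fold changes of -0.52 ± 0.10 (SE) in PC3 at 24 h (adjusted p = 0.001) and -0.30 ± 0.10 in PC3 at 48 h (adjusted p = 0.023). In LNCaP it was lower by -1.70 ± 0.10 at 24 h (adjusted p = 3.1e-10) and -1.74 ± 0.10 at 48 h (adjusted p = 1.1e-10). FOXM1 (probe ILMN_2344971) was lower by -0.58 ± 0.12 in PC3 at 24 h (adjusted p = 0.0011), -0.78 ± 0.12 in LNCaP at 24 h (adjusted p = 5.1e-05) and -1.38 ± 0.12 in LNCaP at 48 h (adjusted p = 1.3e-08). Its change in PC3 at 48 h, -0.20 ± 0.12, did not pass the test (adjusted p = 0.18). The LNCaP fall of MELK exceeded the PC3 fall by 1.18 on the log2 scale at 24 h (adjusted p = 1.6e-05) and by 1.44 at 48 h (adjusted p = 1.6e-07). For FOXM1 the lines differed by 1.18 at 48 h (adjusted p = 9.1e-06) and by 0.20 at 24 h (adjusted p = 0.5).

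The PC3 values of both genes at 48 h stood against DMSO cultures that had themselves changed. MELK had a log2 level of 10.62 ± 0.10 in PC3 DMSO at 24 h and 9.92 ± 0.07 at 48 h, and FOXM1 8.35 ± 0.12 and 7.81 ± 0.12 (SD, n = 3). In LNCaP DMSO the levels were 10.4 ± 0.11 and 10.6 ± 0.06 for MELK, and 8.02 ± 0.16 and 8.14 ± 0.03 for FOXM1. The differences between lines at 48 h thus also hold this step of the PC3 DMSO arrays. They were not tested with the 24 h DMSO arrays as control. The MELK call in PC3 at 48 h was lost without PC3 DMSO 48 h replicate 2 (-0.26, adjusted p = 0.085), without PC3 Siomycin 48 h replicate 2 (-0.26, adjusted p = 0.083) or replicate 3 (-0.29, adjusted p = 0.06). The mean of its 2 probes did not pass either (-0.17, adjusted p = 0.094, from 1.1e-07 to 0.094 over its alternatives). Against the 24 h DMSO arrays, a control added after the data had been seen, it came to -1.005 (adjusted p = 1.1e-07). With median centring in place of quantile normalization the MELK call in PC3 at 24 h was lost (adjusted p = 0.066, from 4.3e-05 to 0.066 over its alternatives). Under the same setting MELK in PC3 at 48 h came to -0.623 (adjusted p = 0.0071) and FOXM1 there became a call (-0.64, adjusted p = 0.0045, from 2.4e-05 to 0.44 over its alternatives).

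**Figure D1:**
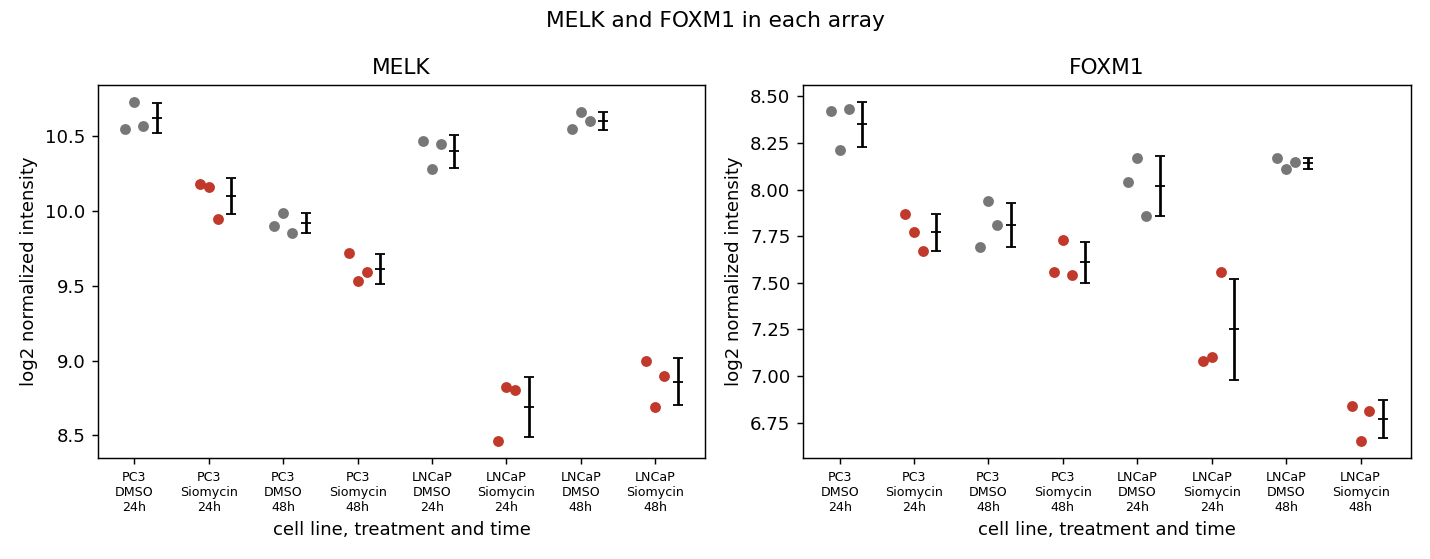
Log2 levels of MELK and FOXM1 on each of the 24 arrays by group, with the group mean and SD (n = 3 arrays per group). In LNCaP the Siomycin arrays of MELK average 8.69 at 24 h and 8.86 at 48 h, below the DMSO averages of 10.40 and 10.60, while in PC3 at 48 h the averages are 9.61 and 9.92.

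In PC3 cells after 24 h of Siomycin A, genes of mitosis and of DNA replication fell while proteasome subunits and genes of several stress programmes rose. The mitosis and FOXM1 target list fell almost as a whole: 36 of its 37 members were lower and none higher (median log2 fold change -0.66, camera adjusted p = 2.1e-25; 37 lower adjusted over the list alone). Among them were CDC25B, a phosphatase that activates mitotic CDKs (-1.07 ± 0.08), and CCNB2, a mitotic cyclin (-0.95 ± 0.08). Of 32 DNA replication and G1/S genes 21 fell and 0 rose (median -0.44, adjusted p = 1.8e-10; 24 lower adjusted over the list alone), led by MCM7, a subunit of the replicative helicase (-0.97 ± 0.14), and UHRF1, which maintains DNA methylation (-0.80 ± 0.15). Proteasome subunits rose together, 26 of 27 (median 0.56, adjusted p = 1.8e-22; 27 adjusted over the list alone). PSMA2 of the core particle was at 1.27 ± 0.11 and PSMC4 of the regulatory particle at 1.09 ± 0.19.

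Targets of ATF4, the transcription factor of the integrated stress response, also rose in PC3 at 24 h: 22 of 26 were higher and 0 lower (median 0.67, adjusted p = 7.2e-23; 24 higher adjusted over the list alone). They included SLC7A11, the cystine importer (2.34 ± 0.10, above background on 1 of 3 DMSO arrays), and DDIT4, an inhibitor of mTOR signalling (2.26 ± 0.09). Of 16 NRF2 oxidative stress genes 15 rose (median 0.85, adjusted p = 1.1e-16). The heme-degrading enzyme HMOX1 was highest at 3.23 ± 0.13, and ABCC3, an efflux transporter, fell by 0.53 ± 0.19. Among 15 ubiquitin and autophagy genes 9 rose and 1 fell (median 0.60, adjusted p = 7.5e-09). GABARAPL1, a protein of the autophagosome membrane, was at 2.87 ± 0.09, the autophagy receptor SQSTM1 at 1.51 ± 0.09 and BECN1 at -0.31 ± 0.09. Glycolysis and hypoxia genes rose in 12 of 15 cases (median 0.74, adjusted p = 2.3e-12; 13 adjusted over the list alone), among them the peptide hormone ADM (1.62 ± 0.22) and NDRG1 (1.62 ± 0.10). The immediate early list rose (6 of 13 higher, 2 lower, median 0.26, adjusted p = 0.0032; 7 higher and 2 lower adjusted over the list alone). The phosphatase DUSP1 was at 2.20 ± 0.09 and ATF3 at 1.13 ± 0.08, but EGR1 and KLF10 both at -0.52. The NF-kB and inflammatory list fell (5 of 14 lower, median -0.38, adjusted p = 0.0042; 7 adjusted over the list alone). The cytokine IL1B was at -1.66 ± 0.10 and the chemokine CXCL1 at -1.02 ± 0.23. Ribosome biogenesis fell too (8 of 17 lower, median -0.36, adjusted p = 6e-05; 9 adjusted over the list alone). NOP16 was at -0.61 ± 0.09 and BOP1 at -0.58 ± 0.09.

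In all, 3066 of 13344 genes differed at 24 h in PC3, 1473 higher and 1593 lower, of which 126 rose and 69 fell by at least 2-fold. The largest rises outside these lists were GCNT3, a mucin glycosyltransferase (4.20 ± 0.12, above background on 1 of 3 DMSO arrays), MLLT11 (2.44 ± 0.11) and probes of the U1 small nuclear RNA of the spliceosome, RNU1-3 (2.44 ± 0.17) and RNVU1-18 (2.44 ± 0.12), whose near-identical copies cannot be separated. The largest falls were PHACTR3, a regulator of protein phosphatase 1 and actin (-3.39 ± 0.12), IGFBP5, a binding protein of insulin-like growth factors (-2.05 ± 0.14), the long noncoding RNA LINC00261 (-1.87 ± 0.18), the adhesion receptor ADGRF1 (-1.62 ± 0.12) and the hyaluronan synthase HAS3 (-1.52 ± 0.12). Lists that did not pass were cytosolic heat shock (adjusted p = 0.27), endoplasmic reticulum chaperones (0.75), p53 targets (0.12), apoptosis regulators (0.49), androgen receptor targets (0.73), cholesterol and fatty acid synthesis (0.73), metallothioneins and zinc (0.73) and histones (0.67). The ABCC3 call (adjusted p = 0.049) was lost without any 1 of the 6 arrays (adjusted p from 0.078 to 0.14, and from 0.00031 over its alternatives). That of BECN1 (adjusted p = 0.018) was lost without PC3 DMSO 24 h replicate 2 (0.077) or 3 (0.067) or PC3 Siomycin 24 h replicate 3 (0.085), in a range of 0.0049 to 0.31. The NF-kB list missed the threshold among the genes detected on all 24 arrays (-0.44, adjusted p = 0.15, from 6.2e-07 to 0.15 over its alternatives). With median centring the call of KLF10 was lost too (adjusted p = 0.082, from 0.00013 to 0.082 over its alternatives).

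After 48 h in PC3 the proteasome, oxidative stress and hypoxia genes were again higher, the immediate early genes were higher, and the mitosis and ATF4 lists held members that went both ways. Proteasome subunits rose in 24 of 27 cases and fell in 0 (median 0.64, adjusted p = 2.3e-12; 25 adjusted over the list alone). PSMD11 was at 1.37 ± 0.14 and PSMA2 at 1.33 ± 0.11. The same list differed by -0.38 between the 48 h and 24 h DMSO arrays of PC3, a comparison added after the data had been seen, and with the 24 h DMSO arrays as control its median was 0.29 (15 higher, 2 lower). For other lists its value stands beside theirs as that of the DMSO arrays. Of 16 NRF2 genes 14 rose and 1 fell (median 0.60, adjusted p = 3.2e-06; DMSO arrays 0.07). HMOX1 was at 3.27 ± 0.13, GSR, which recycles glutathione, at 1.45 ± 0.11 and ABCC3 at -1.54 ± 0.19. Glycolysis and hypoxia genes rose in 13 of 15 cases (median 0.76, adjusted p = 4e-09; 14 adjusted over the list alone; DMSO arrays -0.26). ADM was at 3.28 ± 0.22 and NDRG1 at 2.05 ± 0.10. Immediate early genes rose in 8 of 13 cases and fell in 1 (median 0.80, adjusted p = 1.4e-05; DMSO arrays -0.22). DUSP1 was at 3.57 ± 0.09, the transcription factor KLF6 at 2.04 ± 0.11 and KLF10 at -0.62 ± 0.13, where 2 of 3 probes went that way.

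The mitosis list in PC3 at 48 h had 20 members lower and 6 higher of 37 (median -0.33, adjusted p = 0.024, and adjusted p = 0.29 with an estimated correlation). Its members ran from HMMR, a spindle protein (-1.46 ± 0.10), and CDC25B (-1.32 ± 0.08) to BUB1B, a spindle checkpoint kinase (0.68 ± 0.16), and CDK1, the mitotic kinase (0.55 ± 0.13). In the DMSO arrays of PC3 35 of these 37 genes were lower at 48 h than at 24 h (median -0.76). DNA replication genes did not pass (9 higher and 5 lower of 32, median -0.02, adjusted p = 0.49), beside a difference of -1.26 between the DMSO arrays. The ATF4 list had 16 members lower and 6 higher of 26 (median -0.39, adjusted p = 0.011, and adjusted p = 0.13 with an estimated correlation). The arginine transporter SLC7A1 was at -1.70 ± 0.10 and CHAC1, which degrades glutathione, at -1.63 ± 0.18, but DDIT3, the transcription factor CHOP, at 1.87 ± 0.08 and CTH, an enzyme of cysteine synthesis, at 1.14 ± 0.11. All 26 ATF4 genes were higher in PC3 DMSO at 48 h than at 24 h (median 1.48, adjusted p = 8.3e-42). Against the 24 h DMSO arrays the 48 h Siomycin arrays gave a median of 1.16 for the ATF4 list (23 higher), -1.05 for mitosis (36 lower) and -1.32 for DNA replication (30 lower).

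Cytosolic heat shock genes rose in PC3 at 48 h (11 higher and 2 lower of 18, median 0.37, adjusted p = 0.0026; 11 higher and 3 lower adjusted over the list alone; DMSO arrays -0.73). HSPA1A was at 1.15 ± 0.09, which its near-identical copy HSPA1B makes uncertain, HSPA4L at 0.96 ± 0.14, BAG3 at -0.84 ± 0.09 and DNAJA1 at -0.26 ± 0.06. Cholesterol and fatty acid synthesis genes rose (9 higher and 0 lower of 17, median 0.36, adjusted p = 0.00052; DMSO arrays -0.30). The sterol sensor INSIG1 was at 2.19 ± 0.09 and HMGCS1, an enzyme of mevalonate synthesis, at 1.79 ± 0.09. Metallothioneins, whose copies are uncertain, rose in 6 of 9 cases and fell in 3 (median 0.62, adjusted p = 0.0076, and adjusted p = 0.092 with an estimated correlation; DMSO arrays -0.23). They ran from MT1G (2.23 ± 0.10) and MT1X (2.17 ± 0.08) to MT1F (-0.36 ± 0.10) and MT1H (-0.54 ± 0.15, and -0.351 without PC3 Siomycin 48 h replicate 3, adjusted p = 0.04). Histones, likewise uncertain, rose in 6 of 11 cases and fell in 3 (median 0.42, adjusted p = 0.0053, and adjusted p = 0.066 with an estimated correlation; DMSO arrays 0.36). H2BC21 was at 2.12 ± 0.08, H2BC4 at 1.76 ± 0.12, H2AZ1 at -0.47 ± 0.07 and H4C8 at -0.67 ± 0.09. Ubiquitin and autophagy genes rose in 8 of 15 cases and fell in 2 (median 0.21, adjusted p = 0.022; DMSO arrays 0.33). GABARAPL1 was at 2.76 ± 0.09, ATG5 at 1.11 ± 0.15, UBB at -0.37 ± 0.07 and BECN1 at -0.83 ± 0.09. Ribosome biogenesis fell (10 of 17 lower and 1 higher, median -0.45, adjusted p = 0.013; 11 lower and 2 higher adjusted over the list alone; DMSO arrays -0.16). DKC1 was at -1.11 ± 0.09, NOP56 at -0.85 ± 0.10 and FBL, the rRNA methyltransferase fibrillarin, at 0.40 ± 0.10.

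In PC3 at 48 h 6105 genes differed, 2598 higher and 3507 lower, and 436 rose and 824 fell by at least 2-fold. GCNT3 was at least 31.5-fold higher (adjusted p = 8.2e-17), since it was not well above background in DMSO. Next were CCL26, a chemokine for eosinophils (3.71 ± 0.14), EYA3, a phosphatase and transcriptional coactivator (3.69 ± 0.13, above background on 2 of 3 DMSO arrays), and MLLT11 (3.42 ± 0.11). PHACTR3 fell most (-5.13 ± 0.12), with the interferon-induced antiviral genes OAS2 (-4.15 ± 0.23) and MX1 (-3.62 ± 0.26), LINC00261 (-3.61 ± 0.18) and the secreted lectin REG4 (-3.45 ± 0.11). TENM4, a transmembrane protein of neuronal connections, was not well above background after Siomycin and at least 14.9-fold lower (adjusted p = 5.3e-13). OAS2 was above background on 2 of the 3 Siomycin arrays, LINC00261, REG4 and MT1H on 1 each. Endoplasmic reticulum chaperones (adjusted p = 0.25), p53 targets (0.73), apoptosis regulators (0.6), androgen receptor targets (0.73) and NF-kB genes (0.42) did not pass.

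The PC3 Siomycin 48 h arrays had the lowest mean upper quartile of intensity of the 8 groups, 150.3 ± 18.2 (SD), against 168.5 ± 9.35 in PC3 DMSO 48 h. A pair of arrays in doubt, PC3 Siomycin 48 h replicate 3 and LNCaP Siomycin 24 h replicate 1, were left out together after the data had been seen. The counts then were 3568, 6039, 3203 and 5485 for PC3 24 h, PC3 48 h, LNCaP 24 h and LNCaP 48 h. With median centring the median of all genes in PC3 at 48 h moved by -0.17, and the split became 844 higher and 4509 lower. The calls of BUB1B (0.241, adjusted p = 0.43), CDK1 (0.366, adjusted p = 0.12), DNAJA1 (-0.322, adjusted p = 0.086), FBL (0.206, adjusted p = 0.37), H2AZ1 (-0.35, adjusted p = 0.073) and UBB (-0.237, adjusted p = 0.19), and of the ATF4 list (-0.54, adjusted p = 0.11), were lost. These adjusted p-values were the highest over each gene's alternatives, whose lowest lay between 2.6e-08 and 0.00075. The ATF4 list ranged from 4.6e-17 to 0.13. Its lowest value came with the 24 h DMSO arrays as control, where the list's median was 1.164, opposite in direction to the fall. Other lists moved but passed: mitosis to -0.583, heat shock to 0.229, cholesterol synthesis to 0.062, metallothioneins to 0.177, histones to 0.191 and NRF2 genes to 0.381. With the 24 h DMSO arrays as control the heat shock list turned to -0.29 (adjusted p = 0.056, from 9.8e-10 to 0.056 over its alternatives). Cholesterol synthesis then had a median of 0.12 (adjusted p = 0.2, from 5.4e-12 to 0.2) and metallothioneins 0.42 (adjusted p = 0.053, from 7.6e-11 to 0.092), while histones came to 1.19 and ubiquitin and autophagy genes to 0.59. The call of the ubiquitin and autophagy list was lost with the 6 arrays of the comparison alone (0.207, adjusted p = 0.051, from 3.3e-11 to 0.051 over its alternatives).

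**Figure D2:**
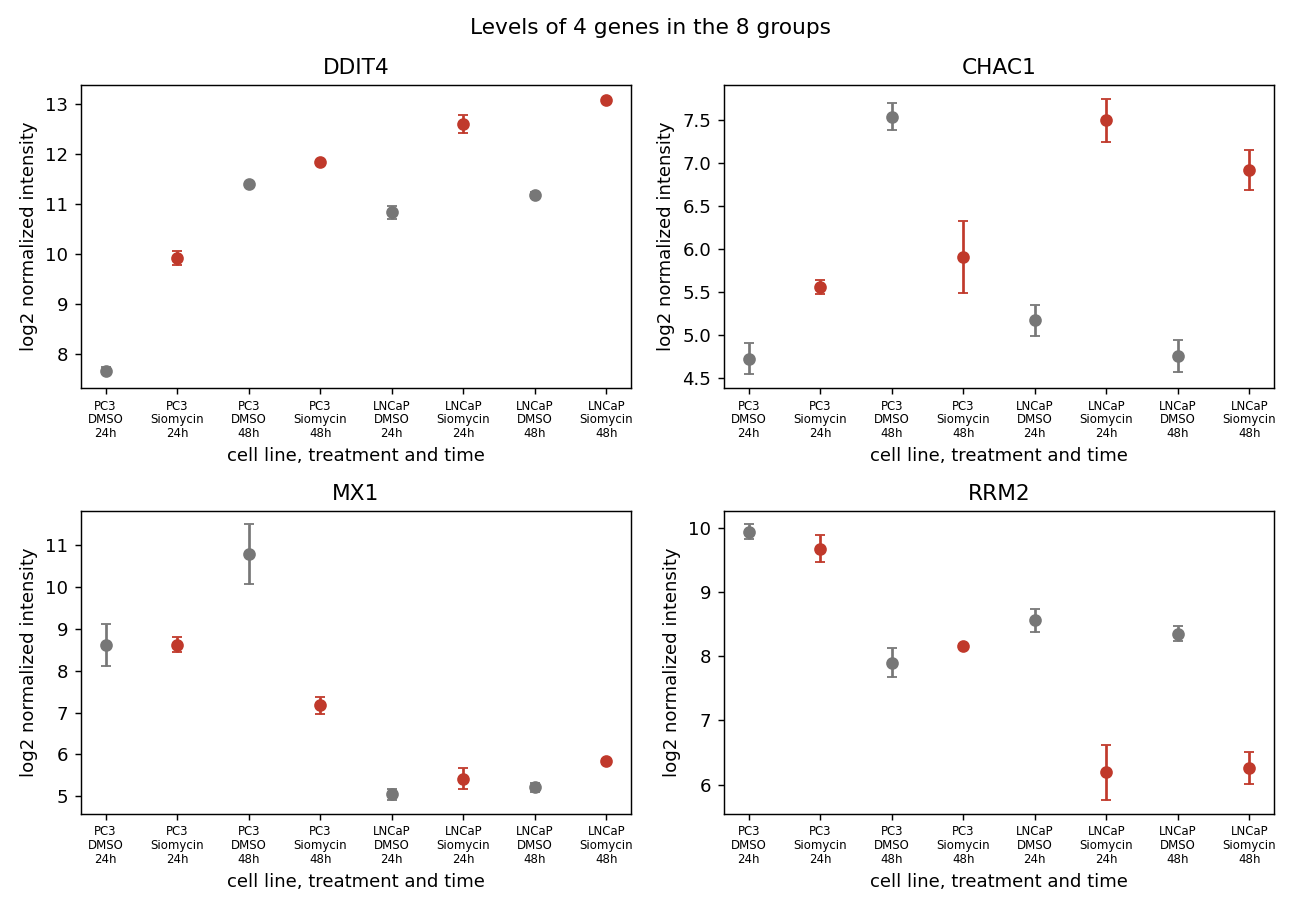
Mean log2 level ± SD (n = 3 arrays) of DDIT4, CHAC1, MX1 and RRM2 in the 8 groups. In PC3 the DMSO level of DDIT4 goes from 7.67 at 24 h to 11.41 at 48 h and that of MX1 from 8.61 to 10.79, while in LNCaP the DMSO levels of DDIT4 are 10.84 and 11.18.

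In LNCaP cells 24 h of Siomycin A lowered genes of the cell cycle and raised ATF4 targets. All 37 mitosis and FOXM1 target genes fell (median -1.37, adjusted p = 1.4e-52; 37 adjusted over the list alone), including the chromosome passenger kinase AURKB (-2.03 ± 0.14) and the cyclin CCNA2 (-1.95 ± 0.09). Of 32 DNA replication genes 31 fell (median -1.44, adjusted p = 8.7e-41), including RRM2, a subunit of ribonucleotide reductase (-2.37 ± 0.17), and CDC45 of the replicative helicase (-2.28 ± 0.17). All 26 ATF4 targets rose (median 1.08, adjusted p = 3e-36; 26 adjusted over the list alone). DDIT3 was at 2.66 ± 0.08 and CHAC1, above background on 2 of 3 DMSO arrays, at 2.33 ± 0.18. Proteasome subunits rose in 9 of 27 cases and fell in 0 (median 0.25, adjusted p = 3.4e-05; 10 adjusted over the list alone). PSMC4 was at 0.82 ± 0.19 and PSMD3 at 0.58 ± 0.12. Without LNCaP Siomycin 24 h replicate 2 the list's median was 0.14 (adjusted p = 0.0011).

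Of 16 NRF2 genes 11 rose and 0 fell in LNCaP at 24 h (median 0.50, adjusted p = 2e-09), among them SLC7A11 (1.61 ± 0.10) and the malic enzyme ME1 (1.15 ± 0.15). Cytosolic heat shock genes fell in 11 of 18 cases (median -0.34, adjusted p = 1.1e-06; 13 adjusted over the list alone). HSPH1 was at -0.84 ± 0.07 and HSPA1B, uncertain beside HSPA1A, at -0.64 ± 0.09. Cholesterol and fatty acid synthesis fell (13 of 17 lower and 1 higher, median -0.45, adjusted p = 7e-07). INSIG1 was at -1.31 ± 0.09 and TMEM97 at -0.79 ± 0.08 on 1 of its 2 probes and 0.35 on the other, and SC5D, which introduces a sterol double bond, at 0.43 ± 0.12. Targets of p53 rose (6 higher and 2 lower of 20, median 0.16, adjusted p = 0.015; 9 higher and 3 lower adjusted over the list alone), with a median of 0.336 without LNCaP DMSO 24 h replicate 2 (adjusted p = 0.0046). The stress cytokine GDF15 was at 1.71 ± 0.09, GADD45A at 0.78 ± 0.10, the exonuclease AEN at -0.37 ± 0.11 and DDB2, above background on 1 of 3 Siomycin arrays, at -0.53 ± 0.13. Metallothionein and zinc genes rose in 5 of 9 cases (median 0.36, adjusted p = 0.00058; 7 adjusted over the list alone). MT2A, of uncertain identity, was at 0.83 ± 0.07 and the zinc-sensing factor MTF1 at 0.62 ± 0.14. Ubiquitin and autophagy genes rose in 6 of 15 cases and fell in 2 (median 0.23, adjusted p = 0.0051). GABARAPL1 was at 1.18 ± 0.09, MAP1LC3B at 0.83 ± 0.08, UBB at -0.21 ± 0.07 and ATG12 at -0.35 ± 0.10. Ribosome biogenesis fell in 10 of 17 cases (median -0.32, adjusted p = 4e-05; 11 adjusted over the list alone). NOP56 was at -0.78 ± 0.10 and NOP16 at -0.65 ± 0.09.

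At 24 h in LNCaP 2779 genes differed, 1396 higher and 1383 lower, with 78 rises and 262 falls of at least 2-fold. NIBAN1, a stress-induced protein, rose most (2.97 ± 0.16), followed by the aldo-keto reductases AKR1C2 (2.94 ± 0.21) and AKR1C4 (2.15 ± 0.20, above background on 2 of 3 DMSO arrays), steroid-metabolising enzymes whose near-identical family makes them uncertain, and the calcium-binding protein S100P (2.38 ± 0.14). The largest falls, beside RRM2 and CDC45, were the exonuclease EXO1 (-2.48 ± 0.18), the spindle protein CKAP2L (-2.15 ± 0.10), the histone chaperone ASF1B (-2.10 ± 0.22) and the mitotic regulator CDCA2 (-2.10 ± 0.12). Endoplasmic reticulum chaperones (adjusted p = 0.45), apoptosis regulators (0.21), androgen receptor targets (0.6), NF-kB (0.3), histones (0.73), immediate early (0.22) and glycolysis genes (0.56) did not pass. Single arrays decided 4 small calls. ATG12 came to -0.269 without LNCaP DMSO 24 h replicate 1 (adjusted p = 0.1) and -0.225 without Siomycin replicate 1 (0.086), and UBB to -0.193 without DMSO replicate 1 (0.12), -0.2 without DMSO replicate 3 (0.1) and -0.134 without Siomycin replicate 2 (0.19). The other 2 were AEN, at -0.249 without DMSO replicate 2 (0.12) and -0.282 without Siomycin replicate 2 (0.09), and SC5D, at 0.309 without Siomycin replicate 2 (0.069). Over all alternatives their adjusted p ranged from 0.0041 to 0.22, 0.0043 to 0.33, 0.00059 to 0.2 and 0.00012 to 0.12, and that of PSMC4 reached 0.11 with the 6 arrays alone, from a lowest of 0.00034.

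After 48 h in LNCaP the cell cycle lists remained lower and the ATF4 list higher, while proteasome subunits no longer rose. All 37 mitosis genes (median -1.39, adjusted p = 4.3e-33) and 31 of 32 DNA replication genes (median -1.53, adjusted p = 1.4e-25) fell. The survivin gene BIRC5 was at -2.20 ± 0.10, AURKB at -2.04 ± 0.14, the flap endonuclease FEN1 at -2.42 ± 0.13 and the replication initiation factor MCM10 at -2.28 ± 0.25. All 26 ATF4 targets rose (median 1.18, adjusted p = 4.6e-26). DDIT3 was at 3.58 ± 0.08 and ATF3 at 2.40 ± 0.08. Of 27 proteasome subunits 12 fell and 0 rose (median -0.18, adjusted p = 0.0071, and adjusted p = 0.1 with an estimated correlation; 13 lower and 1 higher adjusted over the list alone). PSMC3 was at -0.68 ± 0.08 and PSMA2 at -0.52 ± 0.11. Androgen receptor targets rose in 11 of 17 cases and fell in 5 (median 0.74, adjusted p = 0.0058). TMPRSS2 was at 2.02 ± 0.23 and NDRG1 at 1.40 ± 0.10 but the prostatic acid phosphatase ACP3 at -1.31 ± 0.16 and the kinase CAMKK2 at -0.83 ± 0.16. The same list differed by -0.26 between the 48 h and 24 h DMSO arrays of LNCaP, and with the 24 h DMSO arrays as control its median was 0.25 (adjusted p = 0.14, from 1.3e-09 to 0.14 over its alternatives). Its call was also lost among the genes above background on all 24 arrays (0.727, adjusted p = 0.05).

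Heat shock genes fell in 11 of 18 cases in LNCaP at 48 h (median -0.38, adjusted p = 6e-05). HSPH1 was at -1.29 ± 0.07 and CHORDC1 at -1.06 ± 0.15, and cholesterol synthesis fell in 10 of 17 with 1 higher (median -0.34, adjusted p = 0.0043). TMEM97 was at -1.14 ± 0.08 on 1 of 2 probes and 0.21 on the other, the mevalonate kinase MVK, above background on 2 of 3 Siomycin arrays, at -1.03 ± 0.17 and SC5D at 1.08 ± 0.12. Ribosome biogenesis fell in 13 of 17 cases (median -0.56, adjusted p = 1.4e-07). NOP56 was at -1.40 ± 0.10 and NOP58 at -1.32 ± 0.12. NRF2 genes rose in 10 of 16 cases and fell in 1 (median 0.35, adjusted p = 0.0011; 12 higher adjusted over the list alone; DMSO arrays -0.17). SLC7A11 was at 1.60 ± 0.10, HMOX1 at 1.06 ± 0.13 and thioredoxin, TXN, at -0.20 ± 0.07. Targets of p53 rose in 8 of 20 cases and fell in 1 (median 0.18, adjusted p = 0.004; DMSO arrays 0.13; 0.40 with the 24 h DMSO arrays as control). GDF15 was at 2.34 ± 0.09 and GADD45A at 1.85 ± 0.10. ZMAT3, at -0.93 ± 0.18 on the brightest of 3 probes, came to 0.60 with their mean (adjusted p = 2.6e-05, from 6.3e-06 to 0.0031 over its alternatives), so its direction is open. Ubiquitin and autophagy genes rose in 9 of 15 cases and fell in 4 (median 0.43, adjusted p = 0.0044). GABARAPL1 was at 1.82 ± 0.09, WIPI1, above background on 2 of 3 DMSO arrays, at 1.25 ± 0.17, BECN1 at -0.36 ± 0.09 and the segregase VCP at -0.33 ± 0.09. Endoplasmic reticulum chaperones rose in 6 of 17 cases, 7 adjusted over the list alone, and fell in 2 (median 0.18, adjusted p = 0.035, and adjusted p = 0.066 with an estimated correlation; DMSO arrays -0.10). DNAJB9 was at 1.47 ± 0.14, HSPA5, the chaperone BiP, at 1.07 ± 0.11, MANF at -0.37 ± 0.09 and SDF2L1 at -0.33 ± 0.08. Immediate early genes rose in 6 of 13 cases (median 0.19, adjusted p = 0.0067, and adjusted p = 0.054 with an estimated correlation), with ATF3 and KLF6 (1.10 ± 0.11) highest. That median was 0.117 without LNCaP DMSO 48 h replicate 1 and 0.297 without replicate 2, and 0.303 without Siomycin replicate 1 and 0.126 without replicate 3 (adjusted p from 0.0026 to 0.011).

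In LNCaP at 48 h 4987 genes differed, 2530 higher and 2457 lower, with 314 rises and 452 falls of at least 2-fold. S100P rose most (3.93 ± 0.14), then the protease inhibitor SERPINA3 (3.60 ± 0.18), DDIT3, NIBAN1 (3.37 ± 0.16), VLDLR-AS1 (2.65 ± 0.15) and RASD1, a small GTPase (2.61 ± 0.12). The largest falls were the histone gene H2BC11, of uncertain identity (-2.59 ± 0.16), CBLN2 (-2.44 ± 0.24), FEN1, LINC00161 (-2.38 ± 0.21, above background on 2 of 3 Siomycin arrays), the ribosomal protein paralogue RPL22L1 (-2.31 ± 0.08) and the CDK-activating phosphatase CDC25A (-2.31 ± 0.16). Apoptosis regulators (adjusted p = 0.24), metallothioneins (0.24), NF-kB (0.67), histones (0.35) and glycolysis genes (0.43) did not pass. Calls were lost for TXN without LNCaP DMSO 48 h replicate 1 (adjusted p = 0.051) or Siomycin replicate 3 (0.059), in a range of 0.0016 to 0.37, and for the chaperone list without Siomycin replicate 2 (0.051), with median centring (median 0.105, adjusted p = 0.095) and with the 24 h DMSO control (0.112, adjusted p = 0.23), among genes above background on all 24 arrays (0.137, adjusted p = 0.092), and with the 12 LNCaP arrays (0.059) or the 6 arrays (0.1) alone, in a range of 1.6e-08 to 0.23. BECN1 missed the threshold with median centring (adjusted p = 0.061, from 0.001 to 0.061), the NRF2 list with the 24 h DMSO control (median 0.12, adjusted p = 0.24, from 6.1e-09 to 0.24).

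**Figure D3:**
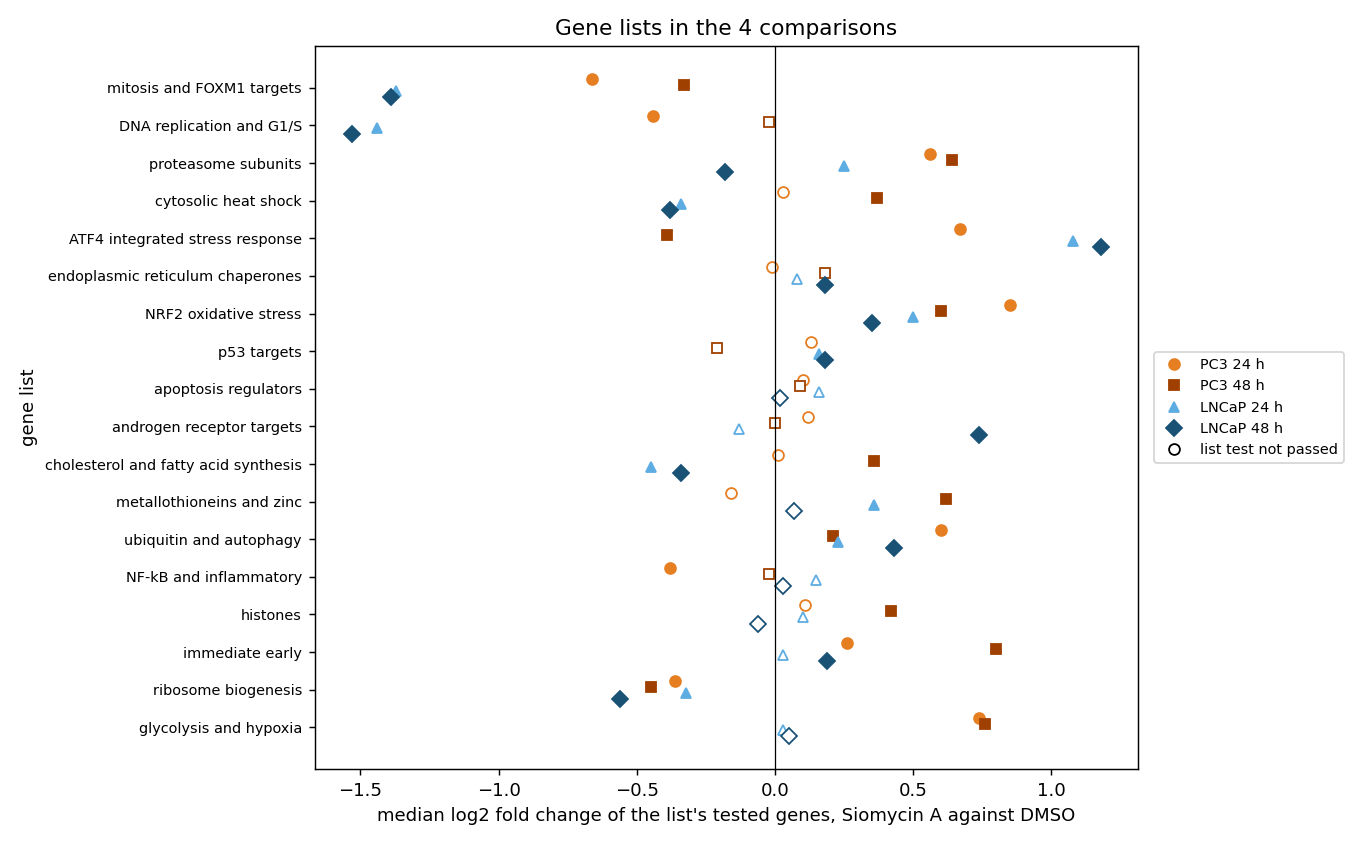
Median log2 fold change of Siomycin against DMSO over the measured members of each of the 18 gene lists, in the 4 comparisons, with filled points where the camera test passed at an adjusted p of 0.05. The ATF4 list lies at 0.67 and -0.39 in PC3 and at 1.08 and 1.18 in LNCaP, the mitosis list at -0.66, -0.33, -1.37 and -1.39.

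The difference between the effects at 48 h and at 24 h was tested within each line, where a positive value means a higher log2 fold change at 48 h. In PC3 3348 genes differed, 1260 positive and 2088 negative, and in LNCaP 1187, 601 positive and 586 negative. Under median centring the PC3 split became 266 and 2576, with the median of all genes moved by -0.20. LNCaP then had 157 calls, 81 positive and 76 negative. The ATF4 list dropped in PC3 (1 positive and 21 negative of 26, 22 negative adjusted over the list alone, median -1.13, adjusted p = 5.8e-19) and gained in LNCaP (6 positive, median 0.20, adjusted p = 3.3e-05). In PC3 the difference was positive for mitosis (15 positive and 1 negative of 37, 18 and 2 adjusted over the list alone, median 0.36, adjusted p = 1.3e-06), DNA replication (14 and 1 of 32, 19 and 2 adjusted over the list alone, median 0.49, adjusted p = 3.7e-07, and adjusted p = 0.1 with an estimated correlation) and heat shock (6 and 1 of 18, 7 and 1 adjusted over the list alone, adjusted p = 0.011). It was also positive for cholesterol synthesis (9 and 1 of 17, adjusted p = 2.3e-05), metallothioneins (4 of 9, 5 adjusted over the list alone, adjusted p = 0.00011), histones (7 and 1 of 11, adjusted p = 1.4e-05), immediate early (5 of 13, adjusted p = 7.4e-05) and glycolysis genes (5 and 2 of 15, 6 and 2 adjusted over the list alone, adjusted p = 0.016). Between the same times the PC3 DMSO arrays differed by 1.48 for the ATF4 list, -1.26 for DNA replication, -0.76 for mitosis, -0.73 for heat shock and -0.30 for cholesterol synthesis. The difference of effects was negative for ubiquitin and autophagy (8 negative and 1 positive of 15, 9 and 2 adjusted over the list alone, adjusted p = 0.016) and NRF2 genes (7 and 1 of 16, adjusted p = 0.026, and adjusted p = 0.15 with an estimated correlation). In LNCaP the proteasome list dropped (12 of 27 negative, 0 positive, median -0.38, adjusted p = 6.8e-13; 19 adjusted over the list alone), as did ribosome biogenesis (6 of 17, adjusted p = 3.1e-05). Androgen receptor targets gained (9 positive and 2 negative of 17, 10 and 3 adjusted over the list alone, median 0.75, adjusted p = 1.2e-05). Targets of p53 (5 of 20, 6 adjusted over the list alone, adjusted p = 0.011), chaperones (3 of 17, adjusted p = 0.0083) and immediate early genes (5 of 13, 6 adjusted over the list alone, adjusted p = 0.00034) also gained in LNCaP. NRF2 genes (1 of 16 negative, adjusted p = 0.036, and adjusted p = 0.17 with an estimated correlation) and histones (4 of 11 negative, 5 adjusted over the list alone, adjusted p = 0.023, and adjusted p = 0.14 with an estimated correlation) dropped.

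Single genes with the largest positive difference in PC3 were EYA3 (2.75 ± 0.18), JMY, a regulator of actin and p53 (2.47 ± 0.22), MT1G (2.41 ± 0.14) and the bombesin receptor GRPR (2.26 ± 0.20). Those with the largest negative difference were MX1 (-3.64 ± 0.36), OAS2 (-3.61 ± 0.33), the homeobox gene MKX (-3.20 ± 0.23) and the ubiquitin ligase TRIM2 (-3.17 ± 0.16). MX1 was 0.02 at 24 h and -3.62 at 48 h, and its DMSO level rose by 2.18 ± 0.26 between these times. The PC3 DMSO level also rose for MKX (2.86 ± 0.16), OAS2 (1.98 ± 0.23) and TRIM2 (0.99 ± 0.12), and it fell for MT1G (-1.45 ± 0.10), EYA3 (-0.88 ± 0.13) and GRPR (-0.57 ± 0.14). TRIM2 was not above background on any PC3 Siomycin 48 h array, so its fitted difference is not an exact value. EYA3 was above background on 2 of 3 PC3 DMSO 48 h arrays and OAS2 on 2 of 3 PC3 Siomycin 48 h arrays. The other probe of JMY gave 0.27, the value for this gene among probes detected on all 24 arrays (adjusted p = 0.39, from 8.7e-11 to 0.39 over its alternatives). In LNCaP they were CFAP69 (1.91 ± 0.19), RASD1 (1.80 ± 0.17), TARP (1.77 ± 0.17) and GLYATL2 (1.76 ± 0.14), against AKR1C2 (-2.21 ± 0.30), RPL22L1 (-2.10 ± 0.11), AKR1C4 (-1.73 ± 0.29) and FAM13B (-1.69 ± 0.19). AKR1C2 had risen by 2.94 at 24 h and stood at 0.73 ± 0.21 at 48 h. AKR1C4 was not above background on any LNCaP DMSO 48 h array, and on 2 of 3 in LNCaP Siomycin 48 h and DMSO 24 h.

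The difference between the lines was tested at each time, where a positive value means a higher log2 fold change in PC3. At 24 h 1900 genes differed, 999 positive and 901 negative, and at 48 h 5766, 2534 positive and 3232 negative, which became 1098 and 3347 under median centring with a shift of the median by -0.15. The 24 h count under that setting was 650, with 378 positive and 272 negative. The cell cycle lists had the less negative change in PC3 at both times. The difference was positive for 28 of 37 mitosis genes at 24 h (median 0.80, adjusted p = 1.5e-20) and 33 at 48 h (median 1.09, adjusted p = 1.2e-17), or 29 with 1 negative and 36 adjusted over the list alone. It was positive for 28 of 32 DNA replication genes at both (medians 0.94 and 1.41, adjusted p = 1.6e-23 and 1.1e-17), or 30 and 29 adjusted over the list alone. Proteasome subunits had the higher change in PC3, 14 of 27 at 24 h (16 adjusted over the list alone, median 0.39, adjusted p = 1.8e-09) and 24 at 48 h (median 0.76, adjusted p = 4e-12). So did heat shock genes (medians 0.34 and 0.88, adjusted p = 2.2e-07 and 1.5e-06), cholesterol synthesis (0.37 and 0.87, adjusted p = 7.4e-06 and 5.6e-06) and glycolysis and hypoxia genes (0.62 and 0.65, adjusted p = 5.7e-10 and 1.1e-05). At 24 h 9 of 18 heat shock, 7 of 17 cholesterol and 10 of 15 glycolysis genes were positive, or 10, 11 and 12 adjusted over the list alone. At 48 h these were 12, 14 and 11, with 1 negative in each. ATF4 targets had the higher change in LNCaP (13 of 26 negative and 2 positive at 24 h, 14 negative adjusted over the list alone, median -0.37, adjusted p = 1.3e-06; 25 at 48 h, median -1.72, adjusted p = 7.4e-20). The PC3 DMSO arrays differed from the LNCaP ones in the 48 h to 24 h step, by 1.52 for the ATF4 list, -1.22 for DNA replication, -0.94 for mitosis, -0.58 for heat shock, -0.43 for cholesterol synthesis, -0.39 for proteasome and -0.27 for glycolysis genes. With the 24 h DMSO arrays of each line as control, the 48 h difference between lines was 0.32 for DNA replication (adjusted p = 0.0078, and adjusted p = 0.32 with an estimated correlation) and 0.21 for mitosis (adjusted p = 0.025, and adjusted p = 0.24 with an estimated correlation). It was 0.42 for proteasome (adjusted p = 2.9e-07), 0.36 for cholesterol synthesis (adjusted p = 0.0011) and 0.45 for glycolysis genes (adjusted p = 0.00013). Heat shock (0.28, adjusted p = 0.18) and ATF4 genes did not pass (median -0.15, with the test pointing up, adjusted p = 0.71).

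At 24 h NRF2 genes (7 positive and 3 negative of 16, 9 and 3 adjusted over the list alone, adjusted p = 0.00034) and ubiquitin and autophagy genes (8 of 15, 9 adjusted over the list alone, adjusted p = 9.5e-05) also differed towards PC3, and NF-kB genes (5 of 14 negative, 7 adjusted over the list alone, adjusted p = 0.00027) and metallothioneins (6 of 9 negative, 6 with 1 positive adjusted over the list alone, adjusted p = 0.0017, and adjusted p = 0.054 with an estimated correlation) towards LNCaP. At 48 h histones (6 and 1 of 11, 6 and 2 adjusted over the list alone, adjusted p = 0.0024, and adjusted p = 0.054 with an estimated correlation), immediate early genes (7 and 3 of 13, 7 and 4 adjusted over the list alone, adjusted p = 0.045, and adjusted p = 0.15 with an estimated correlation) and ribosome biogenesis (6 and 1 of 17, adjusted p = 0.048, and adjusted p = 0.061 with an estimated correlation) differed towards PC3. Targets of p53 differed towards LNCaP (10 negative and 3 positive of 20, 10 and 4 adjusted over the list alone, adjusted p = 0.047, and adjusted p = 0.1 with an estimated correlation). The DMSO step between times differed between the lines by 0.35 for histones, 0.04 for immediate early, -0.12 for ribosome biogenesis and -0.08 for p53 genes. Single genes towards PC3 at 24 h were GCNT3 (4.02 ± 0.17), HMOX1 (2.21 ± 0.19), the galactosidase GLA (2.12 ± 0.10) and RRM2 (2.11 ± 0.25), and towards LNCaP PHACTR3 (-3.44 ± 0.17), AKR1C2 (-2.89 ± 0.30), S100P (-2.05 ± 0.20) and FAM43A (-2.01 ± 0.13). At 48 h they were GCNT3 (5.01 ± 0.17), H2BC11 (4.21 ± 0.23), ADM (3.69 ± 0.32, above background on 1 of 3 LNCaP Siomycin arrays) and MLLT11 (3.55 ± 0.16), and PHACTR3 (-5.09 ± 0.17), S100P (-4.62 ± 0.20), the kinase RPS6KA2 (-4.24 ± 0.10) and MX1 (-4.24 ± 0.36). GCNT3 at both times and PHACTR3 at 48 h were not above background on any LNCaP array of either treatment, so only their change in PC3 was measured. PHACTR3 in LNCaP DMSO 24 h, GCNT3 in PC3 DMSO 48 h and AKR1C2 in PC3 DMSO 24 h were below background as well, and the fitted differences of these genes are not exact values. GCNT3 was above background on 1 of 3 PC3 DMSO 24 h arrays, AKR1C2 on 2 of 3 PC3 Siomycin 24 h arrays and PHACTR3 on 2 of 3 LNCaP Siomycin 24 h arrays.

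Across genes, which are not independent replicates, log2 fold changes at 24 h and 48 h correlated with r = 0.694 in LNCaP (Spearman's rho 0.578) and r = 0.525 in PC3 (rho 0.448). Those of the lines correlated with r = 0.355 at 24 h (rho 0.314) and r = 0.108 at 48 h (rho 0.0998). No control arrays were shared within any of these 4 pairs. At 24 h 489 genes rose in both lines where independent calls would give 154, 564 fell in both (165) and 138 went opposite ways (319). At 48 h 749 rose in both (493), 951 fell in both (646) and 1146 went opposite ways (1143). The 48 h effects rest on DMSO arrays that differed from the 24 h ones in 3774 genes in PC3 and 73 in LNCaP. No correlation was computed with the 24 h DMSO arrays as control. The lower r at 48 h thus cannot be assigned to the response to Siomycin. In all 4 comparisons 234 genes rose and 283 fell. Those that rose by at least 2-fold each time were DDIT3 (1.12, 1.87, 2.66 and 3.58 in PC3 24 h, PC3 48 h, LNCaP 24 h and LNCaP 48 h), GABARAPL1 (2.87, 2.76, 1.18 and 1.82), HMOX1 (3.23, 3.27, 1.02 and 1.06), CTH (1.41, 1.14, 1.53 and 1.75) and the aldehyde dehydrogenase ALDH2 (1.22, 1.49, 1.18 and 2.20). DHRS2, a short-chain dehydrogenase (-1.43, -1.84, -1.23 and -1.76), fell each time, as did TMPO-AS1 (-1.11 in PC3 at 24 h). TMPO-AS1 was not above background on the Siomycin arrays of the other 3 comparisons, where it was at least 2.17-fold, 2.29-fold and 2.28-fold lower in the same order (adjusted p = 3e-06, 2.3e-06 and 3.7e-06). ALDH2 was above background on 2 of 3 PC3 DMSO 24 h arrays and DHRS2 on 1 of 3 LNCaP Siomycin 48 h arrays. ALDH2, DHRS2 and TMPO-AS1 were named after their values were seen.

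**Figure D4:**
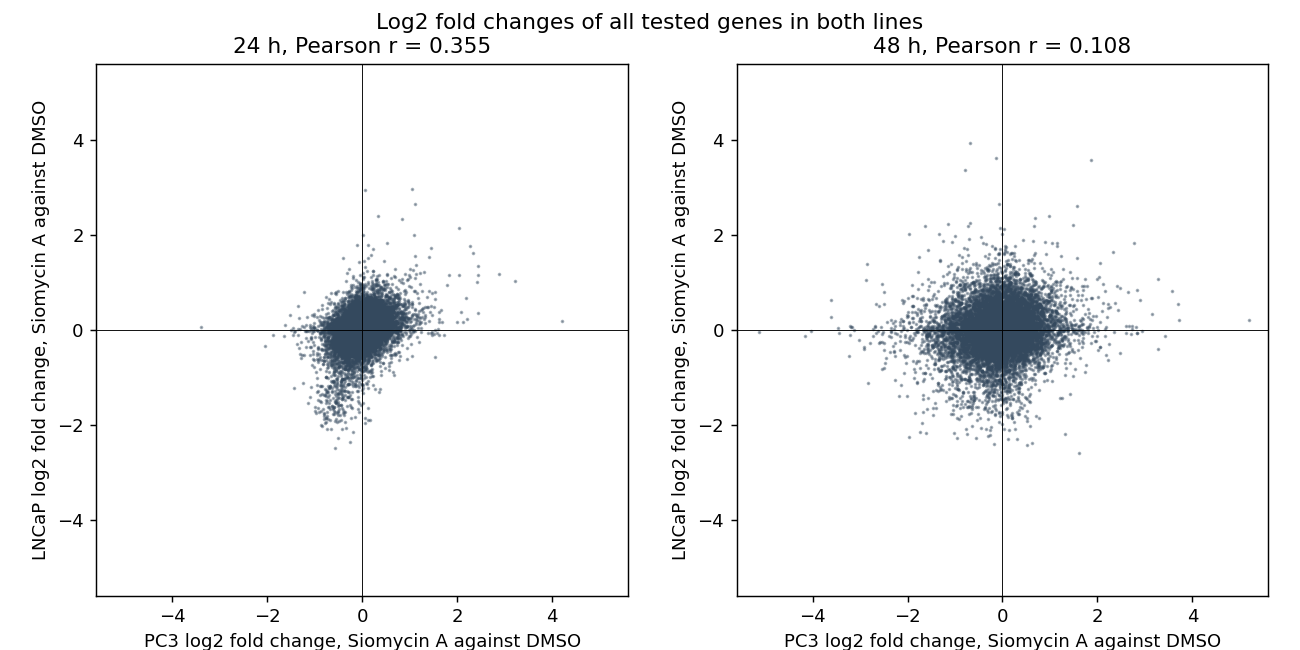
Log2 fold change of Siomycin against DMSO in LNCaP against that in PC3, at 24 h and at 48 h, 1 point per gene (13344 genes). Pearson's r across genes is 0.355 at 24 h and 0.108 at 48 h. The PC3 change at 48 h is taken against DMSO arrays that differed from the 24 h ones in 3774 genes.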

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

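The tests on ATF4 targets, interferon-induced genes, U1 RNA and gene length were chosen after the results they bear on had been seen; the regroupings of arrays were chosen before. For ATF4 targets and interferon-induced genes, the bars for a change of the DMSO cultures were also tightened after their results had been seen, and 1 test of single interferon-induced genes was replaced, which turned those verdicts from decided to open. The bar for a loss of weak signals was tightened as well and then set back to its first form. Unless another contrast is named, the values are tested differences of log2 fold change between lines at 48 h, positive where the change was higher in PC3, and each passed the test of that difference. Those at 48 h rest on PC3 DMSO arrays that differed from the 24 h ones in 3774 of 13344 genes.

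Among cell cycle genes MELK differed by 1.18 at 24 h and 1.44 at 48 h, and FOXM1 by 1.18 at 48 h, and FOXM1 in LNCaP by -0.60 between 48 h and 24 h. CCNA2 (1.99), CDK1 (1.95), AURKB (1.80), CDC25A (2.62), CDCA2 (2.07), EXO1 (1.96), FEN1 (2.23), RRM2 (2.35) and UHRF1 (1.99) differed at 48 h, as did CKAP2L at 24 h (1.95). Between 48 h and 24 h the PC3 DMSO arrays themselves differed by -0.76 for the mitosis list and -1.26 for DNA replication, with RRM2, UHRF1, MELK and FOXM1 lower. The proteasome genes PSMA2 (1.85), PSMD11 (1.71) and PSMD3 (1.59) also differed towards PC3. So did the stress and sterol genes HMOX1 (2.21), GSR (1.55), HSPH1 (1.43), HSPA1A (1.42, uncertain beside HSPA1B and not above background in LNCaP), DUSP1 (2.76), INSIG1 (2.73), HMGCS1 (1.73) and ADM (3.69), and at 24 h GABARAPL1 (1.69).

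Other genes with the higher change in PC3 were GCNT3 (5.01), MLLT11 (3.55), CCL26 (3.50), EYA3 (3.14), GLA (2.79), CBLN2 (2.96), LINC00161 (3.01), RPL22L1 (2.42), RNU1-3 (2.66) and RNVU1-18 (2.58). Members of near-identical families, thus uncertain, were H2BC11 (4.21), H2BC4 (2.50), MT1X (2.12) and AKR1C4 (2.01), while AKR1C2 at 24 h differed towards LNCaP (-2.89). GCNT3 was not above background on any LNCaP array at 48 h, nor RPL22L1 on any PC3 array then, so their change was measured in 1 line only. GCNT3 and CBLN2 in PC3 DMSO 48 h, CCL26 and AKR1C4 in LNCaP DMSO 48 h and AKR1C2 in PC3 DMSO 24 h were likewise below background, and these fitted values are neither exact nor bounds. ADM and CCL26 were above background on 1 of 3 LNCaP Siomycin 48 h arrays, and LINC00161 and AKR1C4 on 2 of 3. So were CBLN2 on 1 of 3 PC3 Siomycin 48 h arrays, EYA3 on 2 of 3 PC3 DMSO 48 h arrays and AKR1C2 on 2 of 3 PC3 Siomycin 24 h arrays.

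The change was higher in LNCaP for the ATF4 and stress genes CHAC1 (-3.80), SLC7A1 (-2.66), DDIT3 (-1.71), GDF15 (-1.66), ATF3 (-1.41) and NIBAN1 (-4.16), and for the interferon-induced MX1 (-4.24) and OAS2 (-4.02). It was also higher there for PHACTR3 (-5.09), S100P (-4.62), RPS6KA2 (-4.24), TENM4 (-4.00), LINC00261 (-3.87), SERPINA3 (-3.74), REG4 (-3.49), CFAP69 (-2.94), VLDLR-AS1 (-2.72), ADGRF1 (-2.44), FAM43A (-2.44), IGFBP5 (-2.33), HAS3 (-1.92) and GLYATL2 (-1.70). Between 48 h and 24 h in PC3 the effect differed for JMY (2.47), MT1G (2.41), GRPR (2.26), H2BC21 (1.98), DDIT4 (-1.82), TRIM2 (-3.17) and MKX (-3.20), beside PC3 DMSO steps of 0.99 ± 0.12 for TRIM2 and 2.86 ± 0.16 for MKX. The PC3 DMSO level of DDIT4 rose by more than that of MKX between these times, and those of MT1G and GRPR fell. On the LNCaP 48 h arrays PHACTR3, TENM4, LINC00261, REG4, OAS2, ADGRF1, IGFBP5 and HAS3 were not above background with either treatment, and on the PC3 48 h arrays neither were SERPINA3 and GLYATL2, so that 1 line alone measured these changes. TENM4 and TRIM2 in PC3 Siomycin 48 h and CHAC1 in LNCaP DMSO 48 h were below background too, which leaves their fitted values inexact. CFAP69, VLDLR-AS1 and OAS2 were above background on 2 of 3 PC3 Siomycin 48 h arrays, and LINC00261 and REG4 on 1 of 3.

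As medians over lists, the lines differed at 48 h for DNA replication (1.41), mitosis (1.09), heat shock (0.88), cholesterol synthesis (0.87), proteasome (0.76), glycolysis and hypoxia (0.65), immediate early (0.53, adjusted p = 0.15 with an estimated correlation), p53 (-0.36, adjusted p = 0.1 with an estimated correlation) and ATF4 genes (-1.72). With the 24 h DMSO arrays as control these differences were 0.32, 0.21, 0.28, 0.36, 0.42, 0.45, 0.59, -0.42 and -0.15 in the same order, beside DMSO steps that differed between lines by -1.22, -0.94, -0.58, -0.43, -0.39, -0.27, 0.04, -0.08 and 1.52. At 24 h the lines differed for NF-kB genes (-0.47) and metallothioneins (-0.58, adjusted p = 0.054 with an estimated correlation). Between 48 h and 24 h the PC3 effect differed for histones (0.58), NRF2 (-0.30, adjusted p = 0.15 with an estimated correlation) and ubiquitin and autophagy genes (-0.47). In LNCaP it differed for androgen receptor targets (0.75), chaperones (0.18) and ribosome biogenesis (-0.25). Outside the gene tests, 7297 probes without 1 named gene held 300 calls in PC3 at 24 h, 1333 in PC3 at 48 h, 312 in LNCaP at 24 h and 928 in LNCaP at 48 h.

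ATF4 targets rose in 3 comparisons but had a median of -0.39 in PC3 at 48 h (adjusted p = 0.13 with an estimated correlation), where the DMSO arrays of both times differed by 1.48. None of the 26 members was below background in either group, and the 22 above it on all 24 arrays also had a median of -0.39, with 14 called lower and 4 higher (camera p = 0.0047, p = 0.099 with an estimated correlation, both unadjusted). Taken array by array, the median over these members, relative to their mean over the 6 arrays, ran from -0.26 to -0.20 with Siomycin and from 0.20 to 0.25 with DMSO, which argues against a loss of weak signals on the dim PC3 Siomycin 48 h arrays as the whole cause. Against the 24 h DMSO arrays the same Siomycin arrays gave a median of 1.16 (adjusted p = 5.8e-17), which follows from the step already seen between the DMSO arrays and adds no evidence of its own. A change of the PC3 DMSO cultures and an effect of Siomycin at 48 h cannot be told apart, since no untreated cultures were analysed here.

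Interferon-induced genes, a list of 32 drawn up after MX1 and OAS2 had been seen, had a median of -1.26 in PC3 at 48 h (27 of 30 lower, 1 higher, adjusted p = 1e-08, but adjusted p = 0.23 with an estimated correlation). The 12 members above background on all 24 arrays had a median of -1.16, with 10 called lower and 1 higher (camera p = 0.00075, p = 0.17 with an estimated correlation, both unadjusted), and array medians from -0.62 to -0.43 with Siomycin against 0.41 to 0.91 with DMSO, which argues against a loss of weak signals as the whole cause. Against the 24 h DMSO arrays its median was -0.21 (adjusted p = 0.58), which follows from the step of 1.05 between the DMSO arrays and adds no evidence of its own. There 12 of the 30 members (40%) were lower, among them MX1 (-1.44 ± 0.26) and OAS2 (-2.17 ± 0.23), and 4 higher, while 28.0% of the other 13314 genes were lower (two-sided Fisher's exact p = 0.16, over genes that are not independent). A change of the DMSO cultures and a lowering by Siomycin cannot be told apart, for the list or for single members.

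Probes of U1 RNA rose in PC3 at 24 h (median 2.43), at 48 h (2.63) and in LNCaP at 24 h (1.16), but stood at -0.05 in LNCaP at 48 h. If more RNA without poly(A) tails had been labelled on the Siomycin arrays, other such RNAs would have risen too, yet 151 other small RNAs and histones had medians of 0.08 (SD 0.32), 0.22 (SD 0.57) and -0.04 (SD 0.32) in the 3 comparisons where U1 rose. Called higher and lower were 13 and 8 of them in PC3 at 24 h, 45 and 9 in PC3 at 48 h, and 9 and 11 in LNCaP at 24 h. In PC3 at 48 h some other small RNAs thus rose as well, by less than U1. The lowest U1 medians over the other settings, 2.08, 2.34 and 0.82 in the same order, came without background correction but with the same quantile normalization. Only median centring scaled the arrays in another way, and it gave 2.35, 2.38 and 1.18. It moved the median of all genes by 0.0015 in PC3 at 24 h, -0.17 in PC3 at 48 h and -0.0084 in LNCaP at 24 h. Such shifts are too small to have removed the rise, so this check decides little about scaling. A treatment effect on U1 transcripts may be put forward as a hypothesis for these 3 comparisons, with no further test, and U1-like copies cannot be told apart by their probes.

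The arrays were regrouped to count the calls that other groupings give. In each of the 4 comparisons and both DMSO comparisons only the real split, 1 of 10, gave as many calls, and 10 splits are too few for a share under 0.05. The real and the highest other counts were 3066 and 0 in PC3 at 24 h, 6105 and 2 in PC3 at 48 h, 2779 and 3 in LNCaP at 24 h, 4987 and 1 in LNCaP at 48 h. They were 3774 and 0 between the DMSO times in PC3, and 73 and 1 in LNCaP. For the differences of effects 1 of 100 regroupings, the real one, gave as many calls each time. The regroupings also mixed Siomycin with DMSO arrays, which breaks up the treatment effects themselves. They therefore do not test whether the effects compared are equal. The replicates may be technical, so chance between cultures is not excluded. The real and highest other counts were 3348 and 332 between times in PC3, 1187 and 7 in LNCaP, 1900 and 342 between lines at 24 h, and 5766 and 2446 at 48 h. Gene length, known for 13333 of the 13344 genes, did not order the changes: Spearman's rho across genes was 0.041, -0.061, 0.071 and 0.124 in PC3 24 h, PC3 48 h, LNCaP 24 h and LNCaP 48 h.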

How the results depend on the processing

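The fit of normexp to each array, the filter on either side of the background, the 24 h DMSO control and the fits without 2 doubted arrays were tested after the data had been seen. Of the alternatives' values, 250 of 277 counts stayed within 1.5 times, 1578 of 1620 list results kept direction and side of the threshold (22 lost and 17 gained a call, 14 of these gains with fry, which tests a list against no change and not against other genes), as did 4074 of 4130 for named genes (55 lost a call) and 164 of 172 for MELK and FOXM1. The 24 h DMSO control was not run for named genes other than MELK and FOXM1. Named genes were mostly chosen for large changes in these same data, which favours calls that hold. The authors' table and no background correction gave equal counts, so they are not separate checks. The called genes numbered 1411 to 4149 in PC3 at 24 h, 4806 to 6507 in PC3 at 48 h, 993 to 4842 in LNCaP at 24 h and 3445 to 5745 in LNCaP at 48 h. The correlations across genes ran from 0.504 to 0.572 between times in PC3, 0.654 to 0.781 in LNCaP, 0.326 to 0.454 between lines at 24 h and 0.101 to 0.131 at 48 h. The 24 h DMSO control was not among the settings run for them.

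Genes changed at least 2-fold numbered 64, 425, 144 and 278 (PC3 24 h, PC3 48 h, LNCaP 24 h, LNCaP 48 h) with no background correction and equally in the authors' table, and 108, 723, 214 and 434 with an offset of 50, since added background compresses changes. Main counts were 195, 1260, 340 and 766. Normexp fitted to each array gave 127 in PC3 at 24 h and 504 in LNCaP at 48 h, and the 7618 genes above background on all 24 arrays 99 and 756 in PC3. Median centring called 1411 genes in PC3 at 24 h, 1305 in LNCaP at 24 h, 157 between LNCaP times and 650 between lines at 24 h, with MELK in PC3 at 24 h at -0.524 (adjusted p = 0.066) and FOXM1 in PC3 at 48 h at -0.642 (adjusted p = 0.0045). Array weights called 4842 genes in LNCaP at 24 h, 2934 between LNCaP times and 3436 between lines at 24 h, where the weights had not converged and LNCaP Siomycin 24 h replicate 3 took 8.85. The count between LNCaP times was 1795 without the 2 doubted arrays and 615 with the 12 LNCaP arrays alone, and the 6 arrays alone called 3311, 5633, 993 and 5274 genes in PC3 24 h, PC3 48 h, LNCaP 24 h and LNCaP 48 h. Apart from the offset and the number of genes, the cause was not tested.

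Of 199 called changes of named genes and 46 of lists, 55 and 9 moved by over 1.5 times with no background correction and as many in the authors' table, 10 and 8 with median centring, 7 and 3 with an offset of 50, and 3 and 1 with array weights (FOXM1 in LNCaP at 24 h to -0.49, PSMC4 to 0.478). The mean of all probes moved 10 genes, among them GSR (0.841), INSIG1 (1.322) and OAS2 (-2.755) in PC3 at 48 h. The 24 h DMSO control moved 11 of 25 lists, the genes above background on all 24 arrays 5 of 46, and leaving out 1 array 3 of 1386 values of genes and 6 of 276 of lists.

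Replicate numbers did not pair the arrays: same-numbered deviations correlated between -0.15 and 0.04, and a Siomycin array correlated best with its own number in 1, 1, 0 and 0 of 3 cases. With the replicate block 693 genes were called between LNCaP times, other counts stayed within 1.5 times, and MELK in PC3 at 48 h had -0.302 (adjusted p = 0.06); AEN, ATG12, UBB, TXN and the LNCaP 48 h chaperone list also lost their calls. ABCC3 and BECN1 in PC3 at 24 h, AEN, ATG12, SC5D and UBB in LNCaP at 24 h and TXN in LNCaP at 48 h lost theirs with median centring. ABCC3 did so with no filter, the filter on either side and the fitted normexp, UBB with no filter, and UBB and ATG12 with the mean of probes. ATG12 lost its call with array weights and without the 2 doubted arrays, AEN, ATG12 and UBB with the 12 LNCaP arrays, and these with SC5D and PSMC4 with the 6 arrays. A slide block was not run, as no slide is named in the sources used here. For MELK in PC3 at 48 h leaving out 1 array gave -0.355 to -0.263 (adjusted p from 0.019 to 0.085) and the mean of its probes -0.167 (adjusted p = 0.094). ZMAT3 in LNCaP at 48 h turned to 0.597 with the mean of its probes, which disagree. With the 24 h DMSO control in PC3 at 48 h FOXM1 came to -0.739, DNA replication to -1.32, heat shock to -0.292 and ATF4 targets to 1.164. With an estimated correlation the medians of mitosis in PC3 at 48 h (-0.332, adjusted p = 0.29) and proteasome in LNCaP at 48 h (-0.179, adjusted p = 0.1) no longer passed. Signal over background limits dim genes: without a filter 20045 genes were tested.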

Other observations

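The comparisons of DMSO arrays between times, and the tests on the list of interferon-induced genes, were chosen after the data had been seen. PC3 cells in DMSO differed between 48 h and 24 h in 3774 of 13344 genes, 1922 higher and 1852 lower at 48 h (158 and 177 at least 2-fold), while LNCaP cells differed in 73 (45 higher, 28 lower). All 26 ATF4 targets were higher at 48 h in PC3 DMSO (median 1.48, adjusted p = 8.3e-42), led by DDIT4 (3.75 ± 0.09) and TRIB3, a pseudokinase of the stress response (3.38 ± 0.08), with ATF4 itself at 1.53 ± 0.07 and asparagine synthetase ASNS at 2.35 ± 0.08. Of the interferon-induced genes 22 of 30 were higher (median 1.05, adjusted p = 6.5e-13), but the list's call was lost with an estimated correlation (adjusted p = 0.19). DNA replication (30 of 32 lower, median -1.26, adjusted p = 2.7e-29), mitosis (35 of 37, median -0.76, adjusted p = 2.4e-24) and heat shock genes (14 of 18, median -0.73, adjusted p = 6.3e-10) were lower, including UHRF1 (-2.16 ± 0.15), RRM2 (-2.03 ± 0.17) and thymidylate synthase TYMS (-1.99 ± 0.08).

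In LNCaP DMSO the ATF4 list had -0.05 (adjusted p = 0.19) and the interferon list 0.05 (adjusted p = 0.41) between the same times, and mitosis 0.12 (adjusted p = 1.9e-06, no member called). The transcriptional regulators ID1 and ID3 were lower at 48 h, by -1.60 ± 0.10 and -1.01 ± 0.11. The step between times differed between the lines in 2452 genes, with a median of 1.52 for ATF4 targets (25 of 26 called, adjusted p = 3.4e-47) and 0.88 for interferon-induced genes (adjusted p = 1.2e-10, but adjusted p = 0.19 with an estimated correlation). Outside PC3 at 48 h the interferon list showed no shift with Siomycin that passed the test: -0.03 in PC3 at 24 h, 0.08 and 0.01 in LNCaP. The genes named here were chosen after their values had been seen.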
